A study of Mus musculus with 16 samples.

How the data were processed

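Total RNA from single retinas of Gtf2ird1 null and WT mice was hybridised to Affymetrix Mouse Exon 1.0 arrays with 1 biotin label, 4 biological replicates in each of 4 groups (null and WT, 2 weeks and 4 months). The titles and the extraction protocol give the older age as 4 months, while the growth protocol gives 2 months; 4 months is used here as the name of the group. The submitters' processing notes name Partek, RMA and the genome build mm8; versions were not given in the sources used here. The deposited values are log2 signals, 1 per transcript cluster and array. The log base was not stated and was inferred from the range of the values, 3.76213 to 15.7311, since a scanner of this kind cannot exceed 16 on the log2 scale. RMA usually includes background correction, quantile normalization and summarisation, but the medians of the arrays differed (5.31 to 5.55), so the deposited summaries were not fully equal in distribution. No further scaling was applied in the reported values.

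The table held 115830 transcript clusters. Of these, 25539 carried the symbol of 1 gene, 2300 carried those of several genes and 87991 carried none. Transcript clusters with 1 gene gave 20259 genes, of which 3109 had several transcript clusters; the one with the highest mean over all 16 arrays stood for the gene. No filter on low signal was applied. A mouse gene table of a later assembly was used only for gene names and for the order of genes along chromosomes, and no coordinates are given. For 885 genes the chosen transcript cluster did not lie in the table among clusters of the gene's own chromosome. Nr2e3, which is in the list of named genes, had no transcript cluster with 1 gene and was not analysed here, and another item is not reported here.

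Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) in 1 model of all 16 arrays with 4 group means and 12 residual degrees of freedom, without covariates. The contrasts were null minus WT at 2 weeks, at 4 months and averaged over the ages, the difference of the first 2 (interaction), and 4 months minus 2 weeks in WT and in null. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The p-values measure the spread between biological replicates, as the labels give them, pooled over the 4 groups. They do not measure the spread of the compared groups alone. Standard errors are those of limma. Single values and list means were compared by two-sided exact permutation tests, whose smallest p for 4 against 4 arrays is 0.0286.

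Gene lists (38, with 709 genes, of which 621 were measured) for retinal cell types, pathways, neighbouring tissues, sex and the chromosome region of Gtf2ird1 were tested with camera (limma) with its preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. Some genes are members of several lists. The lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names Gtf2ird1 and 13 core photoreceptor genes, of which 11 were measured; the 10 largest rises and 10 largest falls among called genes whose 4 arrays of one group all lie above the other 4 (5 each for the interaction, by p where fewer than 5 passed); and up to 4 members of each list described. A list is described where it passed, had 3 or more called members or was one of 8 chosen ones, and the others are summarised together. Predicted genes were counted and not named. Genes outside the rule are said to be such where they are named; the examples of genes called at both ages (Ivd, Ano6, Gbp7) were chosen after their values were seen.

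Whether replicate numbers pair null with WT arrays was checked from the correlation of the residuals of same-numbered arrays; the numbers do not pair them, and the result with replicate as a block is given only among the alternatives. The alternatives were quantile normalization and median centring of the arrays, only genes at or above the median signal, the mean over the transcript clusters of a gene, all transcript clusters of the table, only the arrays compared, eBayes with trend and robust, no moderation of the variances, array weights, the replicate block, a sex covariate from Xist and the Y-linked genes, an adjusted p under 0.1, a fold of at least 1.5, and leaving out each array in turn. Added after the data were seen were leaving out the 3 WT arrays with Xist signal, only genes whose transcript cluster lies among clusters of its own chromosome, a covariate for the mean of the lens list, and the correlation between the ages without WT replicate 1 of 2 weeks. Other splits of the arrays (35 within an age or genotype, 100 drawn over both ages) were refitted. A list of hypoxia-inducible genes, of which 31 were measured, was added after the data were seen.

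The procedure was tested on simulated data with the residual spread of each gene, drawn independently for each gene and array. Of genes changed 1.5-fold, 2-fold and 4-fold, 65.7% of 67, 91.0% of 67 and 98.5% of 66 were called. All 170 had the right sign, and 13 of 183 calls were false. With no gene changed 0 of 20259 genes were called by limma. A shifted list was called by camera, and of 34 lists without shifted members 0 were called. The simulated values held no correlation between genes and no array effects. They therefore do not test the preset correlation of camera, or the false calls of limma where arrays differ as here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.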

Results

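Transcript levels were measured in retinas of mice with a null allele of Gtf2ird1, a gene for a transcription factor of the TFII-I family, and in age-matched wild-type (WT) retinas. Each of the 16 retinal RNA samples was hybridised to its own Affymetrix Mouse Exon 1.0 array. The arrays formed 4 groups of 4 biological replicates: null and WT at 2 weeks of age, and null and WT at 4 months of age. The median log2 signal of an array lay between 5.31 and 5.55, and the number of arrays limits the precision of every value given here. A gene was called when its limma adjusted p (Benjamini-Hochberg over 20259 genes) was under 0.05.

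The first question was whether the targeted gene was lost in the null retinas. Here and below, a probe set means a transcript cluster as described above, not an exon-level unit of the array. Of the 4 probe sets that carry the Gtf2ird1 symbol, 3 were far lower in the null arrays at both ages. Probe set 7007348 read 4.71 ± 0.154 (SD, n = 4) in null and 9.16 ± 0.293 (SD, n = 4) in WT retinas at 2 weeks on the log2 scale, a 21.9-fold difference. At 4 months it read 4.71 ± 0.163 against 9.38 ± 0.116 (SD, n = 4), a 25.6-fold difference. Probe sets 7008286 and 7008402 were lower in null by 13.5-fold and 14.4-fold at 2 weeks, and by 14.9-fold and 25.9-fold at 4 months. For each of these 3 probe sets the 4 null arrays lay below the 4 WT arrays at both ages (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). Probe set 7008782 had the highest mean signal and therefore stood for the gene in the genome-wide test. It read 10.4 ± 0.103 in null and 10.3 ± 0.0330 in WT at 2 weeks (log2 difference 0.17, exact p = 0.0286, limma adjusted p = 0.395). At 4 months its log2 difference was 0.03 (exact p = 0.657). The rows of all 4 probe sets lay apart from rows of the chromosome that carries Gtf2ird1, so their place in the table does not separate them.

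**Figure D1:**
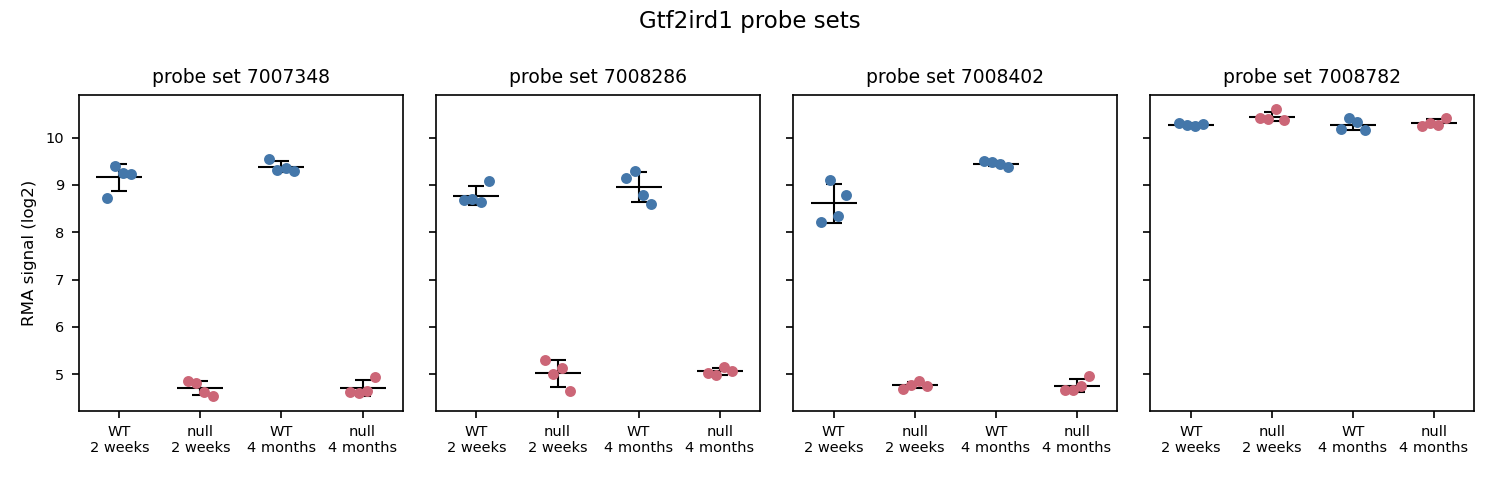
RMA signal (log2) of the 4 probe sets that carry the Gtf2ird1 symbol, 1 point per array, with the group mean and SD (n = 4 per group) as a black bar and whiskers. In probe sets 7007348, 7008286 and 7008402 all null arrays sit below all WT arrays of the same age, and in probe set 7008782 they do not.

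The comparison of null with WT at 2 weeks asked which transcripts differ while the retina matures. Cux2, a homeobox transcription factor, rose most among the called genes of known name, from 6.79 ± 0.169 in WT to 8.74 ± 0.255 in null (SD, n = 4, log2; 3.86-fold, limma adjusted p = 8.8e-07). Fabp7, a fatty acid-binding protein of glia and progenitor cells, rose 3.36-fold, from 7.23 ± 0.0859 to 8.97 ± 0.372 (SD, n = 4). Pde6h, the inhibitory subunit of the cone phosphodiesterase, fell from 7.47 ± 0.244 in WT to 5.93 ± 0.210 in null (SD, n = 4), 2.91-fold lower (limma adjusted p = 0.00038). Ppara, a nuclear receptor for fatty acids, was 2.63-fold lower, and Ercc5, an endonuclease of nucleotide excision repair, was 3.30-fold lower. Ercc2, a helicase of the same repair pathway, fell as well, with a log2 difference of -1.13.

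In all, 214 of 20259 genes were called at 2 weeks, 128 higher and 86 lower in null, and 22 of them had only predicted names. The share that rose was 59.8%, and it became 42.4% after quantile normalization of the arrays and 50.7% after median centring, so the balance of rises and falls is not fixed by these data. Of the called genes, 209 had all 4 null arrays on one side of all 4 WT arrays, as had 1180 of all genes (5.82%, where chance gives about 1 in 35). The other large rises were Haus8, a subunit of the augmin complex of the mitotic spindle (1.69), Cox8b (1.60), Bpifb6 (1.41), the paraoxonase Pon1 (1.29), the relaxin receptor Rxfp1 (1.17), Cltrn (1.16), the matrix protein Thbs4 (1.11) and the mitotic kinase Plk1 (1.09), all as log2 differences with adjusted p between 1.8e-05 and 0.0289. The other large falls were Akr1e1, an aldo-keto reductase (-2.49), Cdcp3 (-2.41), Duxbl1 (-1.41), Lrrc66 (-1.29), the phospholipase Pla2g4e (-1.18) and the histone gene H2ac6 (-1.12), with adjusted p between 0.000327 and 0.00761. The count was 43 with only the arrays compared (37.2% higher), 66 with a lens covariate, 93 with the replicate block, 122 with a sex covariate (44.3% higher) and 491 with array weights. It also depended on single arrays: it was 77 without WT replicate 3, 91 without null replicate 1, 112 without WT replicate 4, 112 without null replicate 3, 138 without null replicate 2 and 525 without WT replicate 1. The calls of Cox8b and Cltrn were each lost in 11 of 31 alternatives with differences no lower than 1.39 for Cox8b and 0.998 for Cltrn, and leaving out any one null array or WT replicate 3 or 4 was enough to lose either call.

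Among the 23 genes of the cone photoreceptor list at 2 weeks, 1 rose, 3 fell and 19 did not pass. Adjusted over the list alone 5 were higher and 7 were lower. The rise was Fabp7, described above as a protein of glia and progenitor cells, and every other called gene of the list fell. The falls were Pde6h, the potassium channel subunit Kcne2 (-0.88, adjusted p = 0.00511) and the cone arrestin Arr3 (-0.59, adjusted p = 0.0283). The call of Arr3 was lost in 10 of 31 alternatives, over which its log2 difference ran from -0.74 to -0.50 and its adjusted p from 0.000246 to 0.233. Leaving out any single 2-week array other than null replicate 4 or WT replicate 1 ended the call of Arr3. The short-wave opsin Opn1sw and the middle-wave opsin Opn1mw did not pass, with log2 differences of 0.30 (adjusted p = 0.102) and -0.30 (adjusted p = 0.0752). Opn1mw passed without WT replicate 1 (-0.31), and so did the cone phosphodiesterase Pde6c (-0.60 over all arrays, -0.82 without that array). The values of Gnat2 (-0.13), Cnga3 (0.24), Thrb (-0.04), Crx (-0.07), Nrl (-0.11) and the rod transducin Gnat1 (-0.01) did not pass, and neither did that of Rxrg (0.66, adjusted p = 0.0660). Rxrg passed without WT replicate 2 (0.79).

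**Figure D2:**
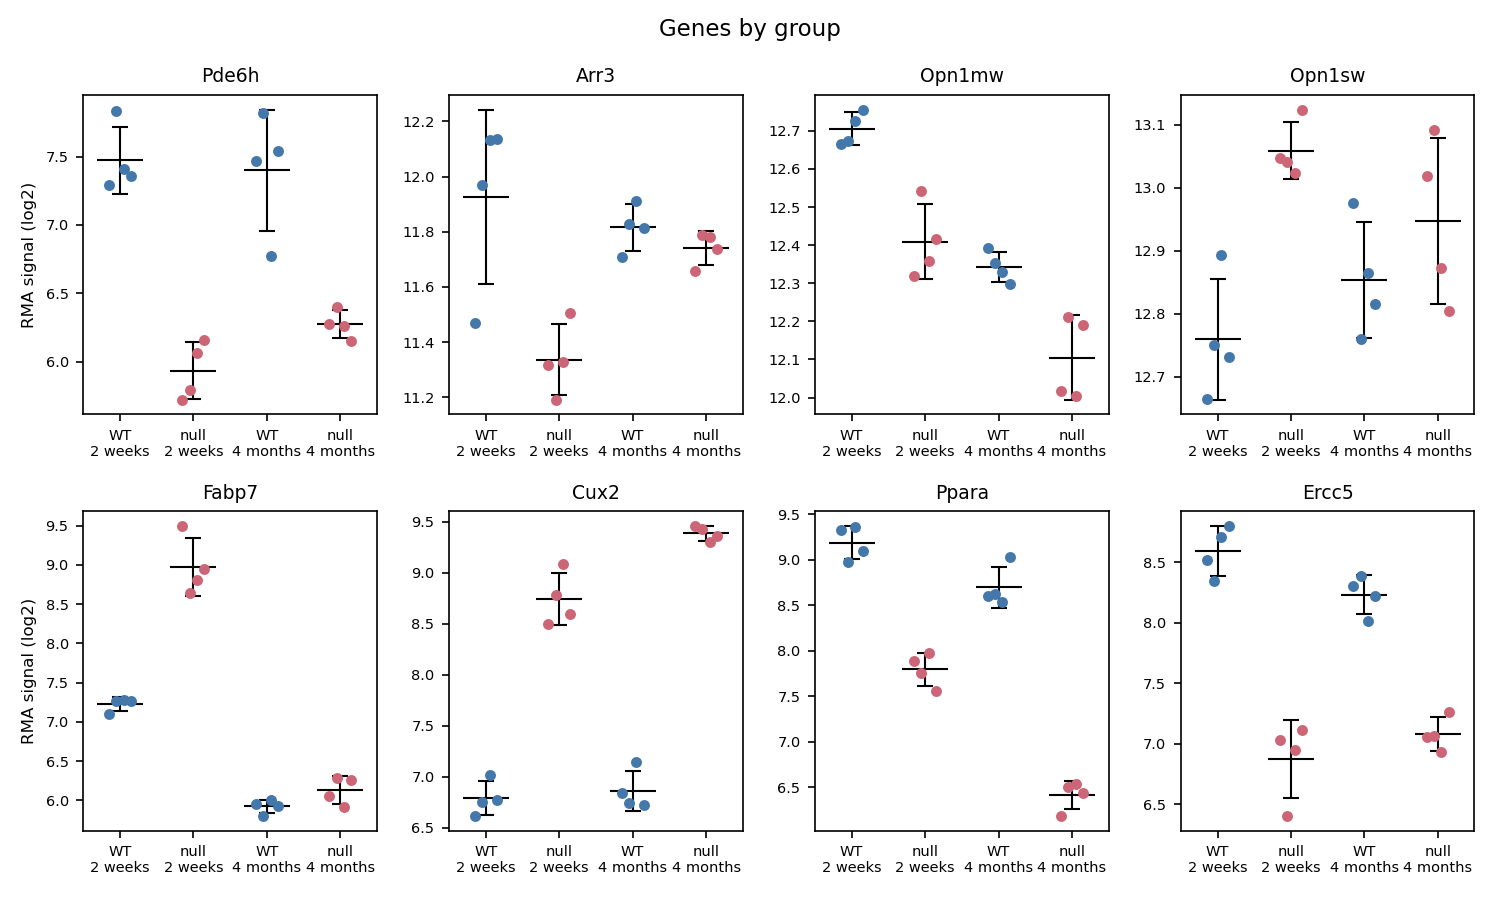
RMA signal (log2) of 8 genes in the 4 groups, 1 point per array, with the group mean and SD (n = 4 per group) as a black bar and whiskers, each panel on its own scale. The null arrays sit below the WT arrays for Pde6h, Opn1mw, Ppara and Ercc5 and above them for Cux2 at both ages. For Opn1sw the null arrays sit above at 2 weeks only, and neither opsin passed at either age over all arrays. The separation of Fabp7 at 2 weeks is reduced to 0.21 on the log2 scale at 4 months.

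Of 27 rod photoreceptor genes at 2 weeks, 1 rose, 1 fell and 25 did not pass; adjusted over the list alone 1 was higher and 2 were lower. The water channel Aqp1 rose by 0.52 and Rp1, a microtubule protein of the outer segment axoneme, fell by 0.55 on the log2 scale. The call of Aqp1 was lost without WT replicate 3, with a log2 difference of 0.51, and that of Rp1 without any one of null replicates 2 and 3 and WT replicates 3 and 4, with values between -0.56 and -0.51. Of 19 pigment epithelium genes, 3 rose and 0 fell at 2 weeks (limma, 2523 of all genes at unadjusted p under 0.05), and adjusted over the list alone 8 were higher. The melanin enzyme Tyr (0.94), the melanosome protein Pmel (0.79) and the keratin Krt18 (0.53) were the rises, and the median of the list was 0.83 (camera adjusted p = 3.6e-10; adjusted p = 0.292 with an estimated correlation). Of 17 lens genes none was called by limma, although 17 had positive differences and 8 were higher adjusted over the list alone. The median of the lens list was 1.96 (camera adjusted p = 7.2e-10; adjusted p = 0.377 with an estimated correlation), and its crystallins and lens filament genes included Crygn (1.75), Crybb3 (2.07), Bfsp2 (2.36) and Bfsp1 (2.87). The other probe sets of Tyr (mean signals 4.86 and 5.22, against 5.50 for the one used) differed by 0.03 and 0.14 and did not pass. Single arrays decided the calls of Tyr (0.86 without WT replicate 3), Krt18 (lost without any one of null replicates 1, 3 and 4 and WT replicates 3 and 4) and Pmel (lost without any one of null replicates 1, 2 and 3 and WT replicates 3 and 4).

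The endothelium and pericyte list (19 genes; 1 rose, 0 fell; 2 higher adjusted over the list alone) had a median log2 difference of 0.12 at 2 weeks, and the vascular growth factor receptor Flt1 rose by 0.69. Without WT replicate 3 the value of Flt1 was 0.59 and without WT replicate 4 it was 0.63, and neither passed. The Muller glia list (22 genes, 2 higher adjusted over the list alone), the glycolysis list (19 genes) and the TGF-beta and BMP list (21 genes) had medians of 0.10, 0.11 and 0.14 with no member called by limma over all genes. The blood list (6 genes, 1 lower adjusted over the list alone) had a median of -0.46. These 5 lists passed the camera test with the preset correlation, at adjusted p of 0.00487 for endothelium, 0.0212 for Muller glia, 0.00487 for glycolysis, 0.0161 for TGF-beta and BMP, and 0.0203 for blood. With an estimated correlation their adjusted p were 0.292, 0.460, 0.324, 0.320 and 0.377, so of the 7 lists that passed at 2 weeks 0 held, and fry called 2 lists, pigment epithelium and endothelium. The number of lists was 4 without null replicate 3 and 4 without null replicate 4. Muller glia did not pass without any one of null replicates 1, 3 and 4 and WT replicates 2 and 4, blood without null replicate 3 or 4 or WT replicate 3, glycolysis without null replicate 4, and TGF-beta and BMP without null replicate 3 or WT replicate 4. Muller glia, blood and glycolysis did not pass after quantile normalization.

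Of 30 genes around Gtf2ird1 on chromosome 5, the tight junction gene Cldn4 fell at 2 weeks (-0.45, adjusted p = 0.0263) and 29 did not pass, with a list median of 0.03; adjusted over the list alone 0 were higher and 1 was lower. The call of Cldn4 was lost in 10 of 31 alternatives. No photoreceptor transcription factor was called among 22 (median 0.08, 2 higher adjusted over the list alone, camera adjusted p = 0.0508). None of 20 microglia and macrophage genes was called (median -0.02, 0 adjusted over the list alone), and none of 21 genes of reactive gliosis and retinal stress (median 0.06, 1 lower adjusted over the list alone). Xist, the transcript of the inactive X chromosome, differed by -4.09 and did not pass (adjusted p = 0.411). It was present in 2 of 4 WT arrays and in 0 of 4 null arrays at 2 weeks, and in 1 of 4 WT arrays and 0 of 4 null arrays at 4 months. Of the sex list (4 genes), 0 were called at either age, over all genes or adjusted over the list alone. The remaining 24 lists had 5 called members in all.

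**Figure D3:**
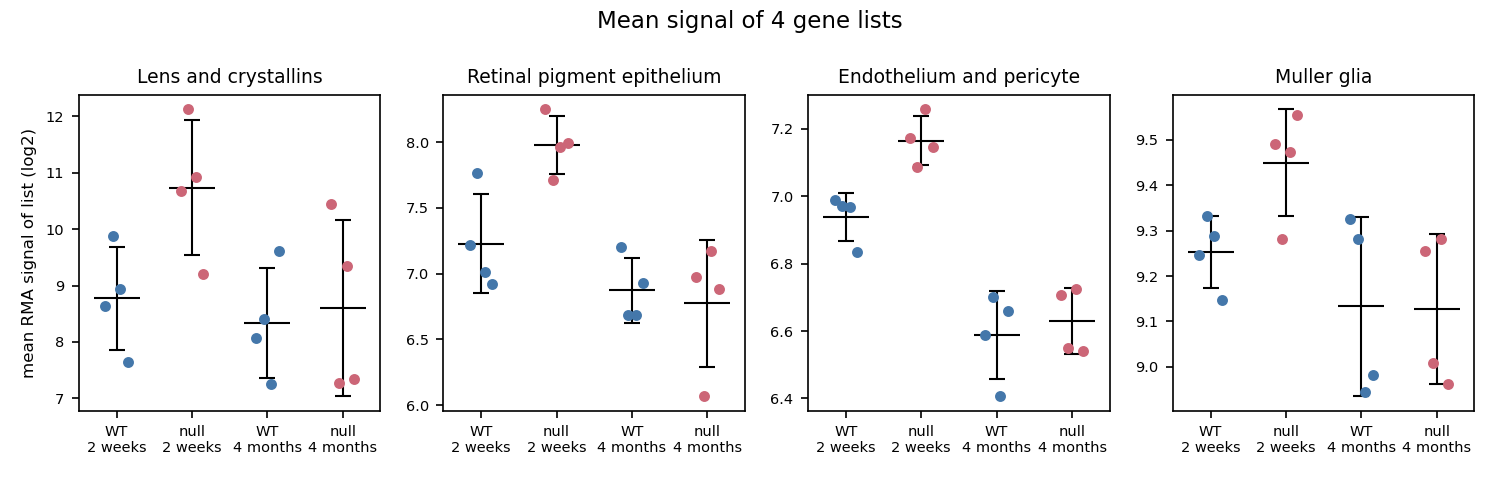
Mean RMA signal (log2) of the genes of 4 lists in each array, with the group mean and SD (n = 4 per group) as a black bar and whiskers, each panel on its own scale. At 2 weeks the lens list averages 10.7 ± 1.20 in null and 8.78 ± 0.916 in WT arrays with overlapping values, and the endothelium list 7.17 ± 0.0716 and 6.94 ± 0.0712 without overlap.

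The same comparison at 4 months asked which transcripts differ in the adult null retina. Cux2 was 5.75-fold higher in null, at 9.39 ± 0.0727 against 6.86 ± 0.194 in WT (SD, n = 4, log2; limma adjusted p = 1.7e-08). Dnajb14, a chaperone partner of the endoplasmic reticulum, was 4.76-fold higher, at 10.1 ± 0.120 against 7.81 ± 0.203 (SD, n = 4). Ppara fell 4.86-fold, from 8.70 ± 0.225 in WT to 6.42 ± 0.159 in null (SD, n = 4, limma adjusted p = 2.6e-08), and Pde6h was 2.19-fold lower. The axonemal dyneins Dnah7b (-1.45) and Dnah9 (-1.20) and the dynein regulatory subunit Drc3 (-1.40) were among the falls, while the cilium and outer segment list (27 genes, 2 fell, median 0.02, mean -0.02) did not pass.

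At 4 months 83 genes were called, 46 higher and 37 lower, of which 9 had only predicted names. In all 83 the 4 null arrays lay on one side of the 4 WT arrays, as they did for 959 of all genes (4.73%, where chance gives about 1 in 35). The actin regulator Eps8l1 rose from 4.63 ± 0.861 in WT to 7.78 ± 0.808 in null (SD, n = 4, log2), with 3 WT arrays at or under 4.23, near the level of absent transcripts, so its difference of 3.16 may understate the rise. The other large rises were Haus8 (2.39), Rxfp1 (1.87), the histone gene H2bc18 (1.79), the hyaluronan receptor Lyve1 (1.28), Slc22a30 (1.27), the matrix protein Postn (1.23) and Tex15 (1.23), with adjusted p between 2.6e-08 and 0.0232. The row of Slc22a30 did not lie among rows of its own chromosome. The other large falls were Cdcp3 (-2.08), Akr1e1 (-1.98), Fndc1 (-1.37), Lrrc2 (-1.21) and Ercc5 (-1.16), with adjusted p between 1.3e-06 and 0.0116. Without null replicate 3 the count was 50, without null replicate 4 it was 54, and without WT replicate 1 of 2 weeks, which enters through the shared estimate of spread, it was 126. The calls of H2bc18 and Postn were lost in 9 and 8 alternatives of 31: leaving out any one null array or WT replicate 1 or 3 of 4 months was enough for both (Postn 1.17 without null replicate 2), as was leaving out WT replicate 4 for H2bc18 (1.62). The call of Slc22a30 was lost without null replicate 3 (1.23) or 4 (1.21).

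Few photoreceptor genes passed at 4 months. Of 23 cone genes, Pde6h fell and 22 did not pass, while adjusted over the list alone 1 was higher and 5 were lower. None of the cone values of Opn1sw (0.09), Opn1mw (-0.24, adjusted p = 0.380), Arr3 (-0.08), Gnat2 (0.07), Pde6c (-0.20), Cnga3 (0.03) and Thrb (-0.15) passed, nor did those of Rxrg (-0.42, adjusted p = 0.663), Gnat1 (-0.07), Crx (-0.03) and Nrl (-0.08). For Opn1mw all null arrays lay below all WT arrays of their age at both ages, though it passed at neither over all arrays. Of 27 rod genes, Aqp1 rose by 0.56 and Rp1 fell by 0.63 on the log2 scale, and 25 did not pass; adjusted over the list alone 1 was higher and 1 was lower. The call of Rp1 at 4 months was lost without null replicate 3, with a log2 difference of -0.57. Of 22 photoreceptor transcription factors 0 were called by limma, and 1 was higher adjusted over the list alone.

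The microglia and macrophage list (20 genes, 0 called over all genes and 0 adjusted over the list alone) was the 1 list that passed the camera test at 4 months, with a median of 0.07 (adjusted p = 0.0376; adjusted p = 0.883 with an estimated correlation). The complement gene C1qb (0.49, adjusted p = 0.270) and P2ry12 (0.43, adjusted p = 0.597) had the smallest p among its members. The list did not pass without null replicate 1 or 3, without any 1 of the 4 WT arrays of 4 months, or without WT replicate 1 of 2 weeks, when 0 lists passed. It also did not pass after quantile normalization, when camera called 0 lists. Without null replicate 2 the number of lists was 4 and without null replicate 4 it was 2. None of 21 gliosis and stress genes was called, over all genes or adjusted over the list alone, although Serpina3n differed by 1.43 (adjusted p = 0.745). The lens list (17 genes, median 0.37, camera adjusted p = 0.545) and the list around Gtf2ird1 (30 genes, median -0.00, mean 0.03) had 0 called members by limma and 0 adjusted over the list alone, with 1087 of all genes at an unadjusted p under 0.05. The other 30 lists had 2 called members in all, and fry called 0 lists.

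The comparisons at the 2 ages share no arrays but share each gene's estimate of spread, and their overlap asked which differences were present at both. Of the called genes, 18 rose at both ages where 0.291 would be expected of independent lists, and 19 fell at both where 0.157 would be expected. The shared estimate makes the lists partly dependent, so these expected numbers are only a rough reference. The 18 included Cux2, Haus8, Rxfp1, Dnajb14, Lyve1, Aqp1, the isovaleryl-CoA dehydrogenase Ivd and the phospholipid scramblase Ano6. The 19 included Ppara, Akr1e1, Cdcp3, Ercc5, Pde6h, Dnah7b, Dnah9, Lrrc2, Rp1, the guanylate-binding protein Gbp7 and Bbs7, a part of the complex that carries proteins to cilia. No gene was called in opposite directions. Of the 214 genes called at 2 weeks 180 had the same sign at 4 months, and of the 83 called at 4 months 74 had the same sign at 2 weeks.

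**Figure D4:**
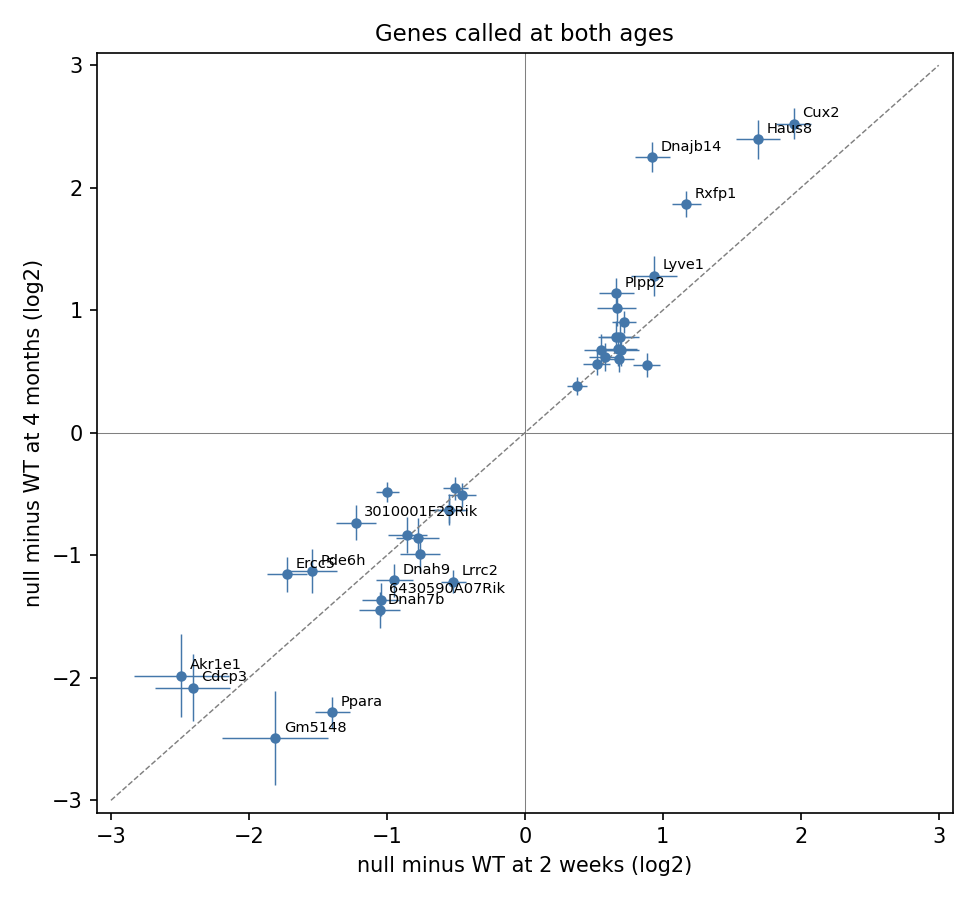
Null minus WT difference (log2) at 4 months against that at 2 weeks for the 37 genes called at both ages, with standard errors as bars and a dashed line of equal differences. The 18 genes that rose lie in the upper right and the 19 that fell in the lower left, and Dnajb14 lies at 0.93 and 2.25.

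Averaged over both ages, 284 genes were called, 145 higher and 139 lower in null, of which 37 had only predicted names. That count was 180 without null replicate 1 of 4 months, 185 without null replicate 1 of 2 weeks, 187 without null replicate 3 of 4 months and 442 without WT replicate 1 of 2 weeks. Across all genes, which are not independent replicates, the differences at the 2 ages had a Pearson r of 0.331 (jackknife standard error 0.180 over arrays) and a Spearman rho of 0.20. Where a gene of the shared set had other probe sets, they did not always move. The other probe set of Ercc5, of similar mean signal (7.48), differed by -0.34 and -0.22 without passing. That of Ano6 (mean signal 6.19) differed by -0.00 and 0.18 and the other 2 of Cr1l (6.21 and 6.13) by 0.21 and 0.19 at 2 weeks, where the probe set used differed by -0.55, and none passed. Of the other 2 of Cux2, the brighter (5.87) differed by 0.27 and 0.15 without passing, and the fainter (4.74) was near the level of absent transcripts, where a change may not show. The other probe set of Haus8 differed by 1.94 and 3.62 and the other 3 of Ppara by -0.62, -1.54 and -1.11 at 2 weeks.

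The interaction of genotype and age asked whether the null minus WT difference changed between the ages. Of the 2 called genes, Fabp7 changed more: it was 1.75 higher in null at 2 weeks and 0.21 higher at 4 months, when it read 6.13 ± 0.177 in null and 5.92 ± 0.0869 in WT (SD, n = 4, log2). Its difference dropped by 1.54 on the log2 scale (limma adjusted p = 0.0107). Dnajb14 went the other way, with a difference that grew by 1.33 (limma adjusted p = 0.0107). These were the only 2 genes called, while 1199 had an unadjusted p under 0.05, and their number was 9 without WT replicate 2 of 2 weeks and 20 without WT replicate 1 of 2 weeks. Neither gene passed with no moderation of the variances, with the replicate block or without the 3 arrays with Xist signal, and Dnajb14 did not pass with the lens covariate, while their differences in these fits ran from 1.22 to 1.33 for Dnajb14 and from -1.54 to -1.49 for Fabp7. In the direction of Dnajb14, the olfactory receptors Olfr686 (1.11) and Olfr684 (0.71), Tapt1 (0.63) and Ip6k3 (1.34) did not pass, and in that of Fabp7, P4ha1 (-0.70), Drc3 (-1.13), Zgrf1 (-0.77) and Lrrc2 (-0.70) did not pass, with adjusted p between 0.101 and 0.147. The change of Arr3 was 0.52 (adjusted p = 0.622) and passed without WT replicate 1 of 2 weeks (0.67), and that of Rxrg was -1.08 (adjusted p = 0.187).

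By the preset camera test 9 lists changed between the ages, and 0 did with an estimated correlation or with fry. Of these, 7 shifted down from 2 weeks to 4 months: pigment epithelium (19 genes, median -0.79), lens (17 genes, -1.57), glycolysis (19 genes, -0.20), TGF-beta and BMP (21 genes, -0.17), Muller glia (22 genes, -0.16), visual cycle (22 genes, -0.13) and photoreceptor transcription factors (22 genes, -0.09). Microglia (20 genes, 0.13) and blood (6 genes, 0.44) shifted up. Pigment epithelium, lens, glycolysis and TGF-beta and BMP passed with each array left out in turn and after quantile normalization, and each of the other 5 was lost without at least 1 array. After quantile normalization 4 lists were called, and the number of lists was 4 without null replicate 3 and 5 without null replicate 4 of 2 weeks. No member of these 9 lists was called by limma over all genes, and adjusted over the list alone 4 pigment epithelium genes, 3 photoreceptor transcription factors and 1 glycolysis gene were lower. Their camera adjusted p were 3.7e-09, 2.3e-06, 1.4e-05, 0.00216, 0.0291, 0.0266 and 0.0268 in the order given for the 7, and 0.0415 and 0.0268 for microglia and blood. With an estimated correlation they were 0.164, 0.449, 0.164, 0.164, 0.449, 0.208, 0.208, 0.449 and 0.449. Of the 23 genes of the cone list 1 passed (adjusted over the list alone 1 higher and 2 lower), Fabp7, a protein of glia and progenitor cells. Of 27 rod genes, 21 gliosis genes, 30 genes around Gtf2ird1 and 4 sex genes 0 passed in limma, over all genes or adjusted over the list alone. The median of the gliosis list was 0.04 while its mean was -0.07.

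The comparison of 4 months with 2 weeks in WT retinas asked how the normal retina changed with age. Glb1l3, a beta-galactosidase relative, rose 5.61-fold, from 7.87 ± 0.553 to 10.4 ± 0.0966 (SD, n = 4, log2; limma adjusted p = 1.5e-05). The histidine decarboxylase Hdc rose 3.91-fold and the cyclic AMP phosphodiesterase Pde8a 3.12-fold. The lens crystallin Cryga fell by 4.48 on the log2 scale, from 9.96 ± 0.511 to 5.48 ± 0.848 (SD, n = 4, limma adjusted p = 0.000892). The mean of the lens list ran from 7.65 to 9.87 in WT arrays of 2 weeks and from 7.26 to 9.61 in those of 4 months. Carried-over lens tissue is a candidate source of lens signal, as given below, and whether the fall of Cryga arose in the retina was not tested. The double homeobox gene Duxbl1 fell by 3.04 and the thyroid hormone deiodinase Dio2 by 1.69. Opn1mw fell by 0.36 (adjusted p = 0.00673) and Gnat1 rose by 0.28 (adjusted p = 0.0264).

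In all, 1861 genes changed with age in WT, 887 higher and 974 lower at 4 months, and 130 of them had only predicted names. The share that rose was 47.7%, and it was 60.1% after median centring and 54.6% after quantile normalization. The groups did not overlap for 1528 of the called genes and for 2581 of all genes (12.7%, where chance gives about 1 in 35). Further rises were Cyp3a44 (1.53), whose row did not lie among rows of its own chromosome, Dnah7b (1.46), the RNA-binding protein Cpeb3 (1.43), Marveld3 (1.41), the elongation factor Tcea3 (1.35), Drc3 (1.34) and the nuclear envelope protein Syne3 (1.34). Further falls were Apobec2 (-2.85), Itm2a (-1.94), the endothelial receptor Adgrl4 (-1.81), the matrix protein Aspn (-1.71), Ube2l6 (-1.67), Olfr1372-ps1 (-1.66) and the potassium channel partner Kcnip2 (-1.64). Other probe sets of Apobec2 (0.31 and 0.01) did not fall, and those of Cpeb3 differed by 0.47 and 0.88, the first without passing. The count was 1117 without WT replicate 3 of 2 weeks and 1226 without WT replicate 1 of 4 months. The age call of Rp1 was lost without any one of WT replicates 2 to 4 of 2 weeks and 1 to 3 of 4 months, with values between -0.40 and -0.35. The call of Gnat1 was lost without WT replicate 3 of 2 weeks (0.23) and without replicate 1 (0.29), 3 (0.29) or 4 (0.26) of 4 months. Of the 3 Gtf2ird1 probe sets that were lower in null, 7008402 rose by 0.84 with age in WT (limma adjusted p = 0.00391 over all probe sets), and 7007348 (0.23) and 7008286 (0.18) did not pass. The probe set that stood for the gene (0.00), Opn1sw (0.09), Arr3 (-0.11), Pde6c (-0.06) and Thrb (0.29, adjusted p = 0.172) did not pass.

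By the preset camera test 5 lists rose with age in WT, 4 of photoreceptor function and the circadian clock, and 0 of them passed with an estimated correlation. Of 27 rod genes 3 rose and 2 fell (adjusted over the list alone 10 and 2; median 0.15). Of 14 genes of phototransduction deactivation 3 rose and 1 fell (6 and 1; median 0.24), with rises of Gucy2e (0.54), Guca1a (0.43) and the rod arrestin Sag (0.31) and a fall of Pdc (-0.51). Of 19 ribbon synapse genes 3 rose, Vamp2 (0.56), Rims2 (0.40) and Bsn (0.59), and 0 fell in limma (5 and 0; median 0.12). Of 27 cilium and outer segment genes 3 rose and 2 fell (5 and 2; median 0.15), among them Spata7 (1.06) and Bbs7 (0.57) upward and Kif3a (-0.56) and Rp1 (-0.40) downward. The other probe set of Spata7, of similar mean signal (7.91), differed by -0.08 and that of Rims2 by 0.19, and neither passed. Of 20 circadian clock genes Bhlhe41 (0.65) and Per3 (0.31) rose and 0 fell in limma (3 and 0; median 0.16). The camera adjusted p of these 5 lists were 0.00124, 0.00124, 0.00148, 0.0253 and 0.00148, and with an estimated correlation 0.399, 0.301, 0.399, 0.425 and 0.251. The cilium list did not pass after quantile normalization, without WT replicate 1 of 2 weeks or without WT replicate 4 of 4 months. The cone list did not pass: of 23 genes 3 rose and 4 fell (5 and 4; median 0.01, mean -0.03), with falls of Fabp7 (-1.30) and Kcne2 (-0.63).

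By the same test 6 lists fell with age in WT, and 0 of them passed with an estimated correlation. Of 19 ganglion cell genes 8 fell and 0 rose in limma (adjusted over the list alone 9 and 0; median -0.25), among them the neurofilaments Nefh (-1.01) and Nefm (-0.67) and the transcription factors Pou4f3 (-0.87) and Isl1 (-0.51). Of 24 amacrine cell genes 6 fell (8 adjusted over the list alone; median -0.16), including the transmitter enzyme Th (-0.81), the peptide Vip (-1.28) and the choline transporter Slc5a7 (-0.74). Of 19 endothelium and pericyte genes 6 fell and 1 rose (8 and 1; median -0.34), with falls of Rgs5 (-0.95) and Esam (-0.71) and a rise of Flt1 (0.90). Of 20 microglia genes 3 fell, Csf1r (-0.44), C1qb (-0.59) and C1qc (-0.42) (5 adjusted over the list alone; median -0.23). Of 16 genes of the unfolded protein response 5 fell (7 adjusted over the list alone; median -0.24), among them Xbp1 (-0.80), Calr (-0.66), Pdia4 (-0.61) and Hspa5 (-0.60). Of 14 genes of iris, ciliary body and muscle 3 fell, Wfdc1 (-1.50), Col9a1 (-1.16) and Actc1 (-0.76) (5 adjusted over the list alone; median -0.16). The camera adjusted p of these 6 lists were 0.00148, 0.00645, 0.00148, 0.00979, 0.00181 and 0.0431, and with an estimated correlation 0.268, 0.399, 0.251, 0.399, 0.268 and 0.399, while fry called 14 lists in all. The microglia list did not pass without WT replicate 1 of 2 weeks. The iris list did not pass after quantile normalization or without null replicate 2, WT replicate 1 or WT replicate 2 of 2 weeks, or WT replicate 3 or 4 of 4 months.

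Further lists had called members without passing the list test. Among 19 bipolar genes 2 rose and 4 fell (adjusted over the list alone 2 and 5), with Prkca upward (0.73) and Tacr3 downward (-0.58), and among 13 horizontal cell genes 1 rose and 4 fell (1 and 4), with Cnih3 (-1.05) and Calb1 (-0.77) downward. Of 22 visual cycle genes 1 rose and 4 fell (2 and 4; median -0.02), and of 19 pigment epithelium genes 3 fell (4 adjusted over the list alone), Tyrp1 (-1.78), Slc26a7 (-0.79) and Pmel (-0.78). Of 22 Muller glia genes 3 fell (5 adjusted over the list alone), Car14 (-0.73), Crym (-0.72) and Slc1a3 (-0.48). Of 21 gliosis genes 2 fell (2 adjusted over the list alone), Edn1 (-0.62) and Gfap (-0.58). Of 11 thyroid hormone pathway genes 1 rose and 3 fell (1 and 4), and of 21 apoptosis genes 1 rose and 2 fell (1 and 3), with Bcl2 upward (1.07) and Gadd45a downward (-0.99). Of 19 progenitor and cell cycle genes 1 rose and 2 fell (1 and 2), with Mki67 downward (-0.59), and of 24 genes of oxidative phosphorylation 1 rose and 2 fell (1 and 2). Of 22 photoreceptor transcription factors 1 rose and 1 fell (2 and 2), Onecut1 (0.40) and Pias3 (-0.51). Of 17 lens genes Cryga fell (1 adjusted over the list alone), of 30 genes around Gtf2ird1 2 rose and 3 fell (3 and 4), of 9 TFII-I family and Williams region genes 1 rose and 2 fell (3 and 2), and of the 4 sex genes 0 were called in limma. The remaining 11 lists had 10 called members in all.

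The same age comparison in null retinas called 1947 genes, 752 higher and 1195 lower at 4 months, of which 121 had only predicted names. The share that rose was 38.6%, and it was 55.6% after median centring and 53.8% after quantile normalization. The null and WT age comparisons share no arrays, but they share each gene's estimate of spread, so expected numbers of independent lists are only a rough reference. In both, 385 genes rose, where 32.9 would be expected of independent lists, and 536 fell, where 57.5 would be expected. None was called in opposite directions, while 4598 genes in null and 4676 in WT had an unadjusted p under 0.05. Glb1l3 reached 11.03 ± 0.0737 in null retinas at 4 months from 8.59 ± 0.477 at 2 weeks (SD, n = 4, log2), and Pde8a 9.41 ± 0.0813 from 7.81 ± 0.180. The count was 1288 without null replicate 4 of 4 months and 1291 without null replicate 1 of 2 weeks.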

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

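The tests of sex and of lens carry-over were chosen after the data were seen. The others here were chosen before, but the relation of the lens list with the pigment epithelium list was tested for a pattern seen in these data.

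In 12 of 200 groups of 4 arrays, 1 array lay far from the other 3 relative to the range of the 4. Chance alone gives about 1 in 20, so this number is close to that of chance, and some of the distances are small. In WT at 2 weeks, Fabp7 read 7.10 in replicate 1 against 7.27 to 7.28 in the others, Ercc2 read 8.98 and Nrl 11.5 in replicate 4 against 8.49 to 8.52 and 11.03 to 11.09, and Ube2l6 read 9.63 in replicate 3 against 7.90 to 8.01, all in log2. In WT at 4 months, Eps8l1 read 5.92, Cryga 6.75 and Pde6c 10.5 in replicate 4 against 4.18 to 4.23, 5.01 to 5.10 and 10.4 in the others. H2bc18 read 7.42 in replicate 2 against 5.71 to 5.91, and in replicate 3 Lyve1 read 7.80 against 8.42 to 8.50 and Cpeb3 9.02 against 9.36 to 9.43. In null retinas, probe set 7008782 of Gtf2ird1 read 10.6 in replicate 3 of 2 weeks against 10.4 in the others, and Pde6c read 10.5 in replicate 4 of 4 months against 10.1 to 10.2.

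The null minus WT difference changed between the ages by 1.33 for Dnajb14 and by -1.54 for Fabp7, in log2, by the interaction test. The median differences of 9 lists changed by the same test with a preset correlation: photoreceptor transcription factors by -0.0865, visual cycle by -0.13, pigment epithelium by -0.79, Muller glia by -0.16, microglia by 0.13, lens by -1.57, blood by 0.44, glycolysis by -0.20, and TGF-beta and BMP by -0.17. With an estimated correlation 0 of the 9 passed in camera (14 lists had an unadjusted p under 0.05 with the preset one). Among the transcript clusters with no gene symbol, which the comparisons leave out, 592 were called at 2 weeks (316 higher) and 148 at 4 months (83 higher), 58 of them at both ages, of 87991.

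In 35 splits of the 8 arrays of each age, 1 gave as many genes as the real one, which was the real one itself: 214 genes at 2 weeks against at most 31 in another split, and 83 at 4 months against at most 63. Over both ages 1 of 100 splits, again the real one, gave 284 genes, and the highest other gave 6. The age comparisons gave 1 of 35 in WT (1861 genes, highest other 453) and 1 of 35 in null (1947 genes, highest other 2). For each of these 5 counts the real split gave the most genes, and its share is the smallest that the number of splits allows. No adjustment was made over the counts, so the splits alone do not exclude chance. For the interaction 4 of 100 splits, the real one included, gave at least 2 genes, which is under 0.05. Regrouping genotype also breaks up the genotype differences common to both ages, so this share does not test the interaction alone. The highest of the 4 splits gave 104 genes, many times the real count, which points to a structure of the samples. It joins null replicates 1 to 3 with WT replicate 1 at 2 weeks, the split that gave 31 genes there, and parts the arrays at 4 months as did the split that gave 63, with null replicates 2 and 4 and WT replicates 3 and 4 together. In these 4 arrays the mean of the Muller glia list was 8.94 to 9.01, against 9.25 to 9.33 in the other 4 of 4 months, a relation seen in the data and not tested further.

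The 37 genes called at both ages are the first pattern weighed. A segment around Gtf2ird1 carried along with the null allele is argued against as their common source, since 1 of them, Cux2, lies within 200 tested genes of Gtf2ird1, where random sets had a median of 1 and a 95th percentile of 2 (permutation p = 0.532); for Cux2 itself it stays open. The uneven sex of the arrays is argued against as well: in arrays without Xist signal their differences at 2 weeks were 1.095 times those over all arrays in the median (lowest 0.715), and 27 of 37 at 2 weeks and 33 of 37 at 4 months were still called. Chromosome segments of another strain, elsewhere in the genome, may contribute, since 3 pairs of the genes (Ercc5 and Dnah7b, Plpp2 and Mier2, Haus8 and Myo9b) lie within 10 tested genes of each other, against a 95th percentile of 2 in random sets (permutation p = 0.0259), and strain variants under the probes would act in the same way. Both tests of gene order placed 35 of the 37 genes, and their random sets were drawn from all placed genes, whatever their signal. The number of pairs alone therefore does not separate such segments from other reasons for neighbouring genes to differ together. All genes called at 2 weeks gave 32 such pairs against a 95th percentile of 27 (permutation p = 0.0040), and those called over both ages 44 against 43 (permutation p = 0.0369). Genes called at 4 months gave 6 against 6 (permutation p = 0.0803). An effect of the loss of Gtf2ird1 stays open beside such segments, since genotype and segments are not separated by this design.

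The higher lens and pigment epithelium signal in null arrays at 2 weeks is the second pattern. Its size was 1.96 for the mean of the lens list (10.7 ± 1.20 in null, 8.78 ± 0.916 in WT; SD, n = 4, exact p = 0.0571) and 0.75 for the pigment epithelium list (exact p = 0.0571), and the brightest lens genes, Cryaa and Cryba1, averaged 13.6 and 12.7 in null against 13.1 and 11.1 in WT. Lens tissue carried over in dissection is a candidate source: within groups, over 16 arrays, the 4 lens genes that are not crystallins followed the crystallins with a Pearson r of 0.979 and a Spearman rho of 0.956 (permutation p = 1e-05, the smallest these permutations allow; r = 0.976 without the 2 farthest arrays), though shared regulation within the retina would give the same relation. In WT at 4 months 15 of the 17 lens genes and 15 of the 19 pigment epithelium genes (5 of them in other lists too) were above every array's median. Tissue carried over in those WT arrays would give this too, so the count does not separate carry-over from expression in the retina. The mean of the lens list ran from 7.26 to 9.61 in them. Whether 1 piece of tissue brought both signals cannot be told apart from separate sources, since the lists correlated at r = 0.428 (rho = 0.297, permutation p = 0.0977, also after adjustment over the 2 relations; r = 0.444 without the 2 farthest arrays), between the bounds set for either answer. An effect of genotype on these genes stays open.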

How the results depend on the processing

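Chosen after the data were seen were the alternatives without the 3 arrays with Xist signal, with genes whose transcript cluster lies among clusters of its own chromosome, with a lens covariate, and the correlation between the ages without WT replicate 1 of 2 weeks. The cause of a change was not tested unless it is given here.

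Counts of called genes were 214 at 2 weeks, 83 at 4 months, 284 over both ages, 2 for the interaction, 1861 for age in WT and 1947 for age in null, in that order below. Testing all transcript clusters gave 846, 230, 956, 20, 6247 and 4136, since more were tested, and turned the balance of the age counts (4253 higher and 1994 lower in WT, 2632 higher and 1504 lower in null). Array weights gave 491, 200, 585, 38, 2903 and 3500. No moderation of the variances gave 108, 49, 185 and 0 for the first 4 (limma's fit; 1199 genes at an unadjusted p under 0.05 in the interaction), and the replicate block 93, 41, 159 and 0; numbers of replicates did not pair arrays (correlations of residuals from -0.28 to 0.23), and age could not be fitted with that block. Only the arrays compared gave 43 at 2 weeks and 855 for age in WT, but 86 at 4 months and 2338 for age in null. Both comparisons that lost calls contain the WT arrays of 2 weeks. With the spread taken from the compared arrays alone, fewer genes were called at 2 weeks than at 4 months, the reverse of the main result. A sex covariate gave 122 at 2 weeks and 168 over both ages. An adjusted p under 0.1 gave 408 at 2 weeks, 129 at 4 months and 2797 for age in WT, and a fold of at least 1.5 gave 137 at 2 weeks, 108 over both ages, 677 for age in WT and 826 for age in null. Without the 3 arrays with Xist signal 230 genes were called at 2 weeks (36.5% higher), of which 105 were among the 214. The differences of the 214 kept their sign, with a median ratio of 1.00 to those over all arrays, though single genes may have changed in size. The interaction gave 10, with neither Fabp7 nor Dnajb14 among them (0 shared). The lens covariate gave 66 at 2 weeks, 153 over both ages, 1 for the interaction and 793 for age in null. The called differences kept their sign, with a median ratio to those without it of 0.999 at 2 weeks and 0.957 for age in null. These medians pool kept and lost calls, of which 62 of 214 at 2 weeks and 737 of 1944 for age in null were kept. The lost calls and their errors were not examined apart, so lens signal as a source of single calls stays open. Quantile normalization, median centring, genes at or above the median, the mean over transcript clusters, trend with robust, and own-chromosome clusters left these counts within 1.5 times.

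Leaving out each array in turn gave 77 to 525 genes at 2 weeks (525 without WT replicate 1, whose array weight was 0.198), 50 to 126 at 4 months, 180 to 442 over both ages, 2 to 20 for the interaction, 1117 to 2606 for age in WT and 1288 to 2655 for age in null. The numbers of lists were 4 to 10 at 2 weeks (7 over all arrays), 0 to 4 at 4 months (1), 4 to 12 for the interaction (9) and 8 to 12 for age in WT (11). The correlation of the differences at the 2 ages ran from 0.219 to 0.412 and was 0.310 without WT replicate 1 of 2 weeks.

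With an estimated correlation camera called 0 lists at 2 weeks, 0 at 4 months, 0 for the interaction and 0 for age in WT, and fry called 2, 0 and 0 for the first 3. With genes at or above the median only, the lists were 3 at 2 weeks, 4 for the interaction and 7 for age in WT. At 4 months quantile normalization, the replicate block, the lens covariate and leaving out the arrays with Xist signal each gave 0 lists and the sex covariate gave 3; quantile normalization gave 4 for the interaction.

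Gtf2ird1 reversed to -2.97 at 2 weeks and -3.31 at 4 months with the mean over its 4 transcript clusters, since 3 of them fell. Of the values of named genes, 5175 kept direction and side of the threshold when 1 array was left out, 43 newly passed and 158 no longer passed; under the other alternatives 4465 kept both, 89 newly passed, 185 no longer passed and 2 reversed. Of the list results, 939, 15 and 54 did so when 1 array was left out and 442, 10 and 82 under the other alternatives. The signal of absent transcripts differs between probe sets (Xist 4.56 to 4.79, Uty 4.19 to 4.65 and Kdm5d 5.05 to 5.77 in arrays that lack them), so falls to such levels, as those of Gtf2ird1 and Cryga, may be larger than given.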

Other observations

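The tests of the hypoxia list here, and the genes that prompted it, were chosen after the data were seen; the test of maturation was chosen before.

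Among genes outside the rule for naming, the hypoxia-inducible peptide Apln (0.91, limma adjusted p = 0.00248) and the collagen prolyl hydroxylase P4ha3 (0.77, limma adjusted p = 0.00323) rose in null retinas at 2 weeks, and the glycolytic regulator Pfkfb3 fell at 4 months (-0.49, limma adjusted p = 0.0268). A list of other hypoxia-inducible genes, which leaves out these and P4ha1, Slc16a3 and Flt1, also seen first, was then tested. Some of its members belong to the glycolysis list, which passed the preset camera test at 2 weeks and for the interaction. The camera p-values of the hypoxia list are not adjusted over other lists. At 2 weeks 23 of its 31 measured genes were higher in null, with a median log2 difference of 0.09, and at 4 months 7 of 31 were, with a median of -0.09 (camera p = 3.2e-05; 0.00048 with an estimated correlation). The change between the ages had a median of -0.20 (camera p = 5.5e-08; 4.6e-05 with an estimated correlation). No single gene of the list was called at either age by limma over all genes. Adjusted over the list alone, 0 were called at either age and 2 for the change between the ages, and of its 24 genes outside the glycolysis list 0 were called at 2 weeks, 3 at 4 months and 3 for the change.

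A hypoxia-like response in the null retinas at 2 weeks is a hypothesis from these values. The camera p of the list at 2 weeks was 0.00269 with the preset correlation and 0.00506 with an estimated one, and 0.0192 without WT replicate 1 of 2 weeks and 0.0345 without the 3 arrays with Xist signal. Outside the glycolysis list, 24 genes gave 0.0469, and 0.260 without WT replicate 1 of 2 weeks and 0.392 without the arrays with Xist signal. The response cannot be told apart from a shift of glycolysis genes and of single arrays, because the result at 2 weeks without glycolysis genes rests on those arrays. At 4 months the camera test of these 24 genes, lower in null, gave 0.000108. Their change between the ages gave 1.6e-05, and 0.000579 without WT replicate 1 of 2 weeks and 0.00294 without the arrays with Xist signal, so the change does not rest on those arrays. Whether the lower level at 4 months rests on single arrays of that age was not tested.

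The null retinas at 2 weeks might have been delayed or advanced in maturation. The WT arrays of 2 weeks were split into 2 and 2, some for the genotype difference and the others for the age difference, so that no array entered both. Over the 6 splits and the 10130 genes at or above the median signal, the correlation across genes of the genotype difference at 2 weeks with the WT age difference averaged -0.0109 and ran from -0.13 to 0.11. With shared arrays the same correlation was 0.204. The 6 correlations differed in sign, which by the rule set beforehand speaks against a general shift in maturation. Their sign depended on the WT arrays used for the genotype difference. Replicates 1 and 4, which have Xist signal, gave -0.13, and replicates 2 and 3 gave 0.11. A small shift can therefore not be excluded, and single genes, such as Fabp7, fell with age in WT and were higher in null at 2 weeks.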
